A study of Danio rerio with 18 samples.

How the data were processed

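Gene expression was measured in cells sorted by fluorescence from zebrafish embryos at 14 to 16 somites, raised at 28 °C. Per the labels, 3 lines were sorted, each into GFP-positive and GFP-negative cells. The first was a wild-type line with a miR-206 reporter, in which the GFP-positive cells are muscle. The second was a wild-type line with a miR-124 reporter, in which the GFP-positive cells are cells of the central nervous system (CNS). The last was a Dicer-mutant line with the miR-124 reporter, named MZ in the labels, an abbreviation they do not spell out. Each of the 6 groups holds 3 arrays, which the labels call biological replicates, and every p-value rests on that description. RNA was extracted with Trizol, and 100 ng of total RNA per sample was labelled with biotin.

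The deposited values are intensity, one linear value per probe set and array, which the authors made from Affymetrix arrays with MAS5 per the submitters' processing notes. The software version, the target of the scaling and detection calls are not given in the sources used here. The values show that each array had been scaled to the same 2% trimmed mean. No read counts exist for arrays, so the number of arrays limits the precision. Of 15617 probe sets, 115 control probe sets were left out of the tests. Of the 15502 others, 10795 had 1 gene symbol in the probe annotation used, 135 had several genes and 4572 had none listed. The gene ID of 10711 of the 1-symbol probe sets was found in a RefSeq table, and 1 symbol was updated from it. These probe sets held 8793 distinct symbols.

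Values were analysed as log2(intensity + 16). A probe set was kept when it lay above the 40th percentile of its own array on at least 3 of the 18 arrays, which left 10704. Where a gene had several such probe sets, the one with the highest mean stood for it. This gave 9548 features, 6831 with a gene symbol and 2717 without a single gene. Probe sets without a single gene were tested but not named.

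A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, which leaves 12 residual degrees of freedom. Variances were moderated with an intensity trend, and p-values of limma's two-sided test were adjusted by Benjamini-Hochberg within each comparison at 0.05. There were 8 comparisons: GFP-positive against GFP-negative cells in each of the 3 lines, mutant against wild type in the GFP-positive and in the GFP-negative miR-124 fractions, the interaction of sort and genotype, muscle against CNS cells, and the GFP-negative cells of the wild-type lines against each other. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so none was used for single genes. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

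The comparisons, the rules and 31 gene lists were fixed before the data were examined. The lists cover sarcomere, myogenic, presomitic, neuronal, neural progenitor, erythroid, endothelial, myeloid, cardiac, epidermal, notochord, hatching gland, endoderm and yolk, neural crest, pronephric, germ plasm, oocyte, cell cycle, ribosomal protein, histone, hox, respiratory chain, glycolytic, microRNA machinery, p53, immediate early, hypoxia and extracellular matrix genes. A further 3 hold reported targets of miR-124, of miR-1 and miR-206 (both in mammals) and of miR-430 (in zebrafish). A list was tested against all other features with limma's camera at a preset correlation between genes of 0.01, if at least 5 members were measured, and p-values were adjusted over all 240 tests of 30 lists. Each test was repeated with an estimated correlation. Counts of members past the threshold are given over all features and adjusted over the list alone. Named genes are the 8 largest rises and the 8 largest falls of each comparison with an adjusted p under 0.05, a gene symbol other than a clone or locus name, and groups that do not overlap (no overlap rule for the interaction), up to 4 members with the smallest adjusted p in the direction of each list past its threshold, and dicer1. Other named genes are marked as such.

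The replicate numbers of the 2 fractions were checked for pairing by the correlation of their residuals. They paired in the miR-206 line (r = 0.367, 0.372 and 0.203) and in the mutant line (0.104, 0.275 and 0.297), where 6 of 6 arrays were closest to their own number. In the wild-type miR-124 line they did not (0.181, 0.003 and -0.086; 2 of 6 arrays). Between lines the result was mixed. It was 5 of 6 arrays for muscle against CNS (0.092, 0.17 and 0.055) and 4 of 6 for rest against rest (0.167, 0.007 and 0.281). For mutant against wild type it was 2 of 6 in CNS cells (0.036, -0.041 and 0.073) and 4 of 6 in the rest (0.086, 0.058 and 0.08). A weak link by number between lines stays open. As the pairing was not uniform, a replicate block was an alternative, not the main model.

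The test was checked on simulated data with 200 of 9548 features changed. At 2-fold, 84% of the changed features were recovered for muscle against rest, 92% for wild-type CNS against rest, 94% for mutant CNS against rest, 90% and 84% for mutant against wild type in the positive and negative fractions, 58% for the interaction, 78% for muscle against CNS and 88% for rest against rest. At 1.5-fold these shares were 30%, 42%, 28%, 30%, 42%, 24%, 46% and 30% in the same order, and at 4-fold between 98% and 100%, as at 8-fold. False calls made up 3.68%, 6.18%, 2.44%, 8.62%, 5.23%, 1.41%, 3.57% and 7.06% of the calls. The simulated noise was normal and drawn independently for each feature and array. These shares therefore do not cover correlation between genes, pairing of arrays or batches in the real data. The real comparisons called more features than the 200 changed here, from 246 to 4242, and the adjusted threshold depends on that share. Changes were added on the log2 scale without a floor for dim probe sets. The shares recovered are thus not the power of the real tests. In the interaction a simulated list that was not shifted had an unadjusted camera p of 0.0254.

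Alternatives were a pseudocount of 1 or 64, quantile normalization, arrays centred on their medians, no filter or one at the 60th percentile, every probe set tested, a fit of only the arrays compared, no intensity trend, array weights, a replicate block, a fold change of at least 2, and leaving out each array in turn. Leaving out wild-type miR-206 GFP-negative replicate 1 and wild-type miR-124 GFP-negative replicate 2 together, the arrays least correlated with their replicates, was chosen after seeing the data. Sets of genes with microRNA sites in their 3' ends were not analysed here, since no genome or transcript sequence was at hand. Groups of 3 arrays are too small for a test for outlying arrays.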

Results

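Expression was compared between cells that carried a microRNA reporter and the remaining cells of the same zebrafish embryos, in 2 wild-type lines and in a Dicer-mutant line. Dicer is the enzyme that cuts microRNA precursors into mature microRNAs, and miR-206 and miR-124 are microRNAs of muscle and of the nervous system. Each of the 6 sorted groups had 3 arrays. Median intensities lay between 30.9 and 44.7 across the 18 arrays. Correlations between replicates lay between 0.962 and 0.990, and those between arrays of different groups between 0.784 and 0.972. Means below are intensities with their SD (n = 3), and changes are log2 fold changes, with their standard error (SE) where given, whose median was 0.17 and 0.24 for the interaction. Where a gene is named for one of the largest changes, its groups did not overlap in any array. Changes of genes dim in one of the groups depended on the pseudocount: with 64 in place of 16, 180 of 514 named values shrank by over 1.5 times, and with 1, 68 grew by as much.

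The first comparison asked which transcripts mark the GFP-positive muscle cells of the miR-206 line. The slow myosin heavy chain gene smyhc1 was highest, at 3422 ± 794 in muscle cells against 58.3 ± 48.4 in the GFP-negative rest, a log2 fold change of 5.69 (SE 0.31, adjusted p = 1.69e-11). The Z-disc gene actn3b rose from 21.3 ± 3.26 to 818 ± 62.7 (4.48, SE 0.17), and the fast troponin gene tnni2b.1 from 50.3 ± 20.0 to 1716 ± 17.4 (4.75). Further large rises were those of the troponin C gene tnnc2.2 (4.77), the myosin light chain gene myl1 (4.67), the sarcomere assembly gene klhl41b (4.52), the calcium pump gene atp2a1 (4.51) and tmem38a (4.47), which encodes a cation channel of the sarcoplasmic reticulum. Among the falls, the claudin gene cldni dropped from 1806 ± 245 in the rest to 26.4 ± 30.7 (-5.64), the neural transcription factor gene sox3 from 2685 ± 645 to 55.0 ± 47.8 (-5.42) and the ectodermal factor gene tfap2a from 1991 ± 188 to 41.7 ± 32.3 (-5.26). The cell adhesion gene epcam (-4.98), sox19a (-4.63), the heart and fin factor gene hand2 (-4.56), gpa33a (-4.40) and the forebrain factor gene otx1 (-4.37) completed the largest falls.

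Of 38 measured sarcomere genes, 35 rose and 0 fell in muscle cells, and 35 rose adjusted over the list alone (mean 2.88, adjusted p = 8.42e-35, and 0.0313 with an estimated correlation). Among 12 myogenic regulators 9 rose and 0 fell, the same numbers as adjusted over the list alone (mean 1.67, adjusted p = 2.56e-08, and 0.0451 with an estimated correlation). They included the muscle determination and differentiation factors myod1 (2.80), myog (3.92; 1203 ± 290 against 63.3 ± 3.26) and mef2d (3.56), and the myoblast fusion gene jam2a (3.03). Of 18 presomitic and early somite genes 12 rose and 2 fell, or 13 and 2 adjusted over the list alone (mean 1.28, adjusted p = 1.18e-06). Examples were the somite factor gene tcf15 (3.92), aldh1a2 (3.78), which makes retinoic acid, and fn1b (3.02). That list had an adjusted p = 0.262 with an estimated correlation. Of 34 hox genes 15 rose and 3 fell, also when adjusted over the list alone (mean 0.40, adjusted p = 0.000116, and adjusted p = 0.36 with an estimated correlation), with hoxc6b at 2.01 and hoxb10a at 1.29.

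Genes of other tissues fell in the muscle cells. Among 54 neural progenitor genes 44 fell and 2 rose, or 45 and 3 adjusted over the list alone (mean -1.85, adjusted p = 6.47e-19, and 0.0313 with an estimated correlation), with sox2 at -4.08 and zic5 at -4.09. Of 33 epidermal genes 26 fell and 0 rose, or 28 and 0 adjusted over the list alone, among them cldnb (-3.24) and cfl1l (-4.10). The epidermal mean was -2.03 (adjusted p = 1.16e-12, and adjusted p = 0.144 with an estimated correlation). All 10 measured myeloid genes fell (10 adjusted over the list alone; mean -1.77, adjusted p = 1.06e-05, and 0.0451 with an estimated correlation), including the white cell factor gene cebpa (-3.92) and the collagenase gene mmp13a (-4.20). Of 43 neuronal genes 33 fell and 2 rose, or 34 and 2 adjusted over the list alone (mean -1.33, adjusted p = 2.79e-11, and adjusted p = 0.123 with an estimated correlation), with myt1a at -3.69. Erythroid genes fell in 16 of 20 cases, as they did adjusted over the list alone (mean -1.68, adjusted p = 5.61e-07, and adjusted p = 0.262 with an estimated correlation), with the blood factor genes lmo2 at -1.92 and klf17 at -2.72. Cell cycle genes also fell, 37 of 59, or 41 adjusted over the list alone (mean -0.50, adjusted p = 1.56e-06, and adjusted p = 0.2 with an estimated correlation), with cdk2 at -1.17 and the nucleotide reductase gene rrm1 at -1.39.

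Genes reported as targets of miR-1 and miR-206 in mammals were lower in the muscle cells, which are the cells sorted for the miR-206 reporter. Of 31 measured, 17 fell and 4 rose, or 18 and 5 adjusted over the list alone (mean -0.76, adjusted p = 0.00244, and 0.0313 with an estimated correlation). Examples were hand2 (-4.56), the growth factor receptor gene met (-2.31), the actin-binding thymosin gene tmsb4x (-1.96) and tagln3b (-1.85). Reported miR-124 targets fell too, 15 of 33 with 4 higher, or 15 and 5 adjusted over the list alone (mean -0.70, adjusted p = 0.0233, and adjusted p = 0.433 with an estimated correlation), with dlx2a at -3.87, tagln2 at -3.60 and the filament gene vim at -3.37. Both lists hold genes known from other tissues of the embryo. Immediate early and dissociation stress genes fell in 17 of 38 cases with 2 higher, the same adjusted over the list alone (mean -0.55, adjusted p = 0.00855, and adjusted p = 0.492 with an estimated correlation), with jun at -1.16.

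In all, 3456 of 9548 features differed in this comparison, 1248 higher and 2208 lower, and 1282 of them by at least 2-fold. The groups did not overlap for 42.4% of the features, where chance gives 10%. The higher share of the changed features, 36.1%, became 57.0% with arrays centred on their medians and 48.3% with quantile normalization, as the median of all genes moved from -0.06 to 0.12 and 0.05. Ribosomal protein genes, 14 higher and 0 lower of 72 (1 and 0 adjusted over the list alone; mean 0.30, adjusted p = 1.35e-08, and adjusted p = 0.492 with an estimated correlation), did not pass with quantile normalization (mean 0.09, adjusted p = 0.131).

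**Figure D1:**
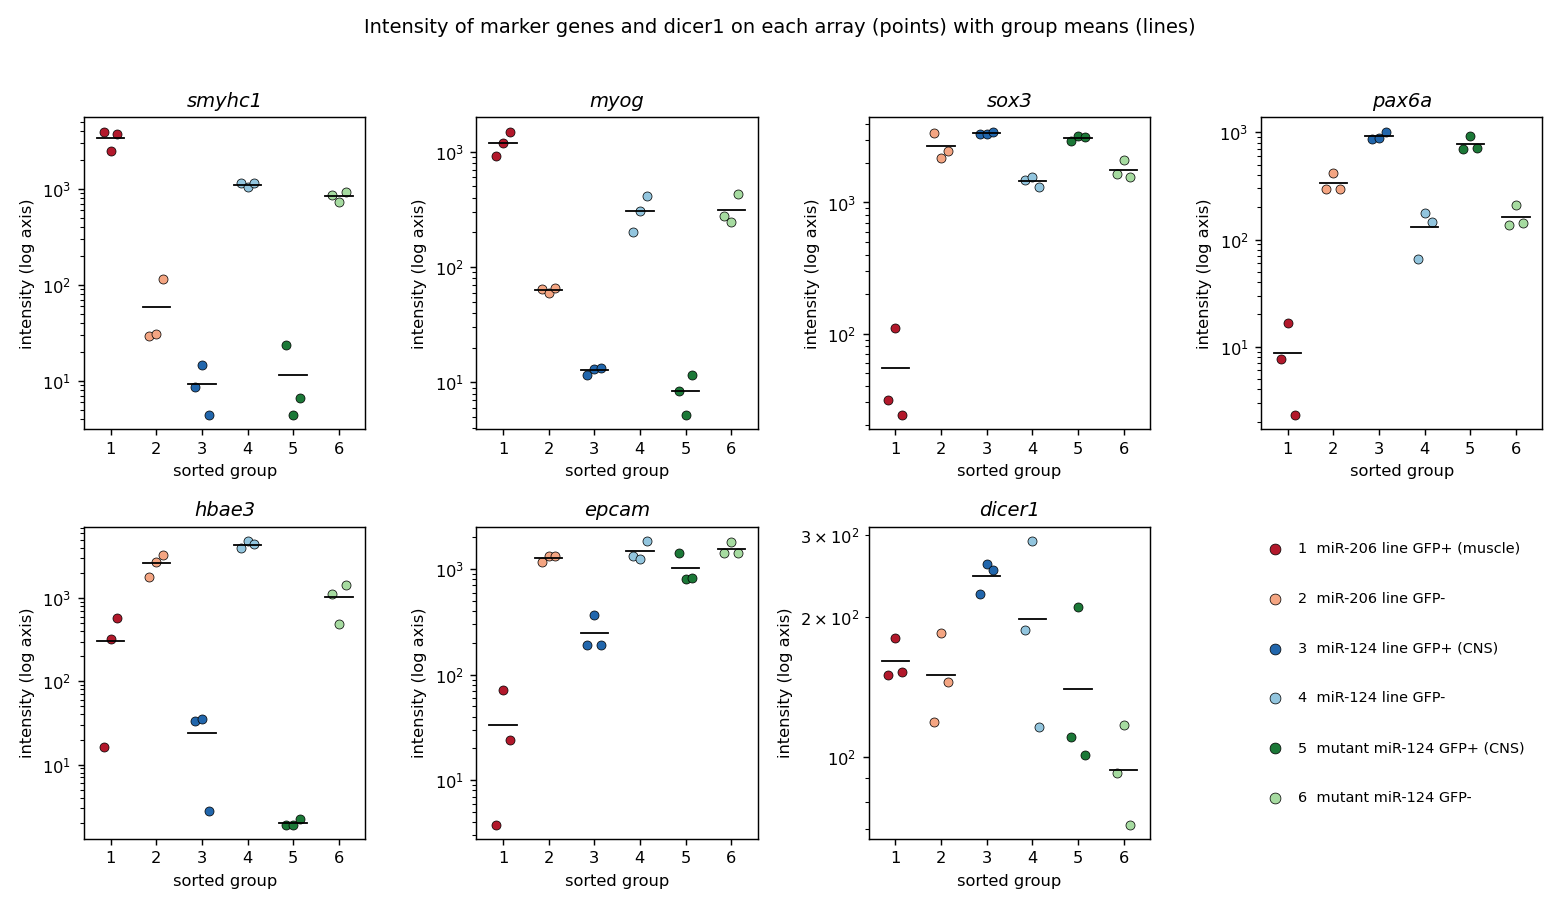
Intensity (log axis) of marker genes and dicer1 on each array (points), with the mean of the 3 arrays (lines), for the 6 sorted groups. The muscle gene smyhc1 averaged 3422 in muscle cells against 58.3 in the GFP-negative cells of that line, and dicer1 averaged 245 in wild-type against 140 in mutant CNS cells.

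In the wild-type miR-124 line, the question was which transcripts mark the GFP-positive CNS cells. The neural stem cell factor gene nr2e1 rose from 20.6 ± 5.79 in the rest to 322 ± 1.12 (3.22, SE 0.18, adjusted p = 4.7e-11). The midbrain and hindbrain boundary gene en2b rose from 81.3 ± 38.4 to 789 ± 35.5 (3.13), its relative en2a by 2.95 and the eye and forebrain gene pax6a from 130 ± 57.3 to 928 ± 75.9 (2.78). The other large rises were those of mab21l2 (2.71), mab21l1 (2.45), ptprna (2.41) and sox19a (2.40). The globin genes hbae3 and hbbe3 fell most, from 4411 ± 446 to 23.7 ± 18.1 (-6.93, SE 0.67) and from 2112 ± 116 to 13.6 ± 2.25 (-6.17). Next came smyhc1, which dropped from 1114 ± 58.0 to 9.23 ± 5.12 (-5.50), the actin gene actc1a (-5.05), cebpa (-4.98), the blood and vessel gene drl (-4.80), the titin gene ttn.2 (-4.75) and the muscle chaperone gene hsp90aa1.1 (-4.75).

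Neural progenitor genes rose in these cells, 44 of 54 with 2 lower, or 44 and 3 adjusted over the list alone (mean 1.16, adjusted p = 1.75e-18, and 0.0313 with an estimated correlation), among them otx1 (2.37), six3a (2.28) and fezf2 (1.90). Cell cycle genes rose as a group, 53 of 59 with 0 lower, or 55 and 0 adjusted over the list alone (mean 0.69, adjusted p = 6.67e-18, and 0.0313 with an estimated correlation). The DNA ligase gene lig1 (1.06), the condensin gene ncaph (1.05), the mitotic kinase gene cdk1 (0.97) and the spindle motor gene kif11 (0.76) were among them. Neuronal genes were divided, 16 higher and 6 lower of 43, or 17 and 6 adjusted over the list alone, with lhx5 at 2.37, stmn4 at 1.95 and olig2 at 1.64. Their mean was 0.30 (adjusted p = 0.0123, and adjusted p = 0.56 with an estimated correlation), and without GFP-negative replicate 1 it was 0.16, which did not pass (adjusted p = 0.126).

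Muscle, blood, skin and trunk genes fell in the wild-type CNS cells. Sarcomere genes were lower in 35 of 38 cases, and in 35 adjusted over the list alone (mean -2.12, adjusted p = 2.99e-23, and 0.042 with an estimated correlation). Of 27 extracellular matrix genes 25 fell, and 25 adjusted over the list alone (mean -1.50, adjusted p = 4.95e-14, and 0.0391 with an estimated correlation), with the collagen genes col5a2a (-3.16) and col1a1a (-2.99) and the matrix gene postnb (-3.24). Among 20 erythroid genes 19 fell, as adjusted over the list alone (mean -2.95, adjusted p = 4.04e-17, and adjusted p = 0.068 with an estimated correlation), with lmo2 at -4.08. Epidermal genes fell in 32 of 33 cases, also adjusted over the list alone (mean -1.76, adjusted p = 1.79e-15, and adjusted p = 0.109 with an estimated correlation), with the keratin genes krt8 at -2.72 and krt18a.1 at -3.39. Of 34 hox genes, which pattern the trunk and hindbrain, 28 fell and 0 rose, as adjusted over the list alone (mean -1.10, adjusted p = 1.05e-12, and adjusted p = 0.0785 with an estimated correlation). Presomitic genes fell in 16 of 18 cases, or 17 adjusted over the list alone (mean -2.13, adjusted p = 9.34e-13, and adjusted p = 0.0989 with an estimated correlation), with fn1b at -4.16. All 10 endothelial genes fell, and 10 adjusted over the list alone (mean -2.34, adjusted p = 2.3e-09, and adjusted p = 0.144 with an estimated correlation), with fli1 at -2.87. Cardiac genes fell in 8 of 9 cases, or 9 adjusted over the list alone (mean -2.21, adjusted p = 6.7e-09, and 0.0313 with an estimated correlation), myeloid genes in 9 of 10, also adjusted over the list alone (mean -2.07, adjusted p = 1.49e-07, and 0.0313 with an estimated correlation). Endoderm and yolk genes fell in 8 of 9, also adjusted over the list alone (mean -1.88, adjusted p = 2.32e-07, and 0.0313 with an estimated correlation), and notochord genes in 9 of 13 with 1 higher, or 11 and 1 adjusted over the list alone (mean -1.40, adjusted p = 5.04e-07, and 0.0383 with an estimated correlation).

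Reported miR-124 targets fell in the cells sorted for the miR-124 reporter, 18 of 33 with 1 higher, or 19 and 3 adjusted over the list alone (mean -0.72, adjusted p = 5.09e-05, and adjusted p = 0.144 with an estimated correlation). Examples were the caveolin gene cav1 (-2.57), the scaffold gene iqgap1 (-2.52), plp2b (-2.35) and the mesenchymal factor gene snai2 (-2.29). Altogether 3129 features differed, 1385 higher and 1744 lower, and 1133 by at least 2-fold. The groups did not overlap for 43.1% (chance 10%). With arrays centred on their medians the higher share moved from 44.3% to 57.8% and the median of all genes from 0.02 to 0.13.

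CNS cells of the Dicer-mutant line were compared with the rest of the same mutant embryos. Here mab21l1 rose by 2.32, otx1 from 205 ± 64.5 to 1037 ± 93.5 (2.29), nr2e1 from 23.5 ± 4.01 to 171 ± 38.2 (2.23), lhx5 by 2.19, en2b by 2.18, pax6a by 2.16, the Notch target gene her4.5 by 2.07 and sox21b by 2.05. The globin gene hbae3 fell from 1019 ± 480 to 2.00 ± 0.173 (-5.72), hsp90aa1.1 from 2965 ± 417 to 59.7 ± 32.9 (-5.38), hbbe3 by 5.43 and smyhc1 by 5.03 on the log2 scale. The mesodermal genes aldh1a2 (-4.77), drl (-4.61), ttn.2 (-4.53) and tbx16 (-4.46) followed.

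Neural progenitor genes rose in 43 of 54 cases with 0 lower, or 44 and 1 adjusted over the list alone (mean 1.06, adjusted p = 2.18e-27, and 0.0313 with an estimated correlation). Of 43 neuronal genes 24 rose and 3 fell, or 29 and 3 adjusted over the list alone (mean 0.69, adjusted p = 4.1e-11, and adjusted p = 0.126 with an estimated correlation), with stmn4 at 1.64 and olig2 at 1.62. Sarcomere genes fell in 29 of 38 cases, or 31 adjusted over the list alone (mean -1.79, adjusted p = 1.01e-28, and 0.0313 with an estimated correlation). Presomitic genes fell in 14 of 18, or 17 adjusted over the list alone (mean -2.55, adjusted p = 2.66e-23, and 0.0313 with an estimated correlation), with the tail genes tbxta at -3.13 and pcdh8 at -3.06. For hox genes the count was 26 lower of 34, or 27 adjusted over the list alone (mean -1.19, adjusted p = 1.67e-22, and 0.0313 with an estimated correlation), with hoxb10a at -2.69. Erythroid genes fell in 17 of 20 cases, also adjusted over the list alone (mean -2.36, adjusted p = 2.33e-20, and 0.0459 with an estimated correlation), with gata1a at -3.35. Cell cycle genes were higher in 6 of 59 cases, or 0 adjusted over the list alone (mean 0.25, adjusted p = 3.98e-06, and adjusted p = 0.213 with an estimated correlation). Of 33 epidermal genes 5 fell, and 5 adjusted over the list alone (mean -0.38, adjusted p = 0.0061, and adjusted p = 0.573 with an estimated correlation). Without mutant GFP-negative replicate 2 the epidermal mean was -0.31 and did not pass (adjusted p = 0.052). Reported miR-124 targets fell here as well, 8 of 33 with 1 higher, or 8 and 3 adjusted over the list alone (mean -0.29, adjusted p = 0.00772, and adjusted p = 0.36 with an estimated correlation). Of 10 oocyte and maternal transcripts 4 fell and 0 rose, or 4 and 3 adjusted over the list alone (mean -0.77, adjusted p = 0.0269, and adjusted p = 0.237 with an estimated correlation). That list did not pass without mutant GFP-positive replicate 2 (-0.70, adjusted p = 0.0544), without a filter (adjusted p = 0.0657) or with a pseudocount of 64 (adjusted p = 0.053).

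Of the 30 lists 21 passed in this comparison, 8 of them also with an estimated correlation, and not all are given here. Cardiac (mean -1.43), endoderm and yolk (-1.45), endothelial (-1.49) and extracellular matrix genes (-0.85), which fell in wild-type CNS cells, fell in mutant CNS cells too. In total 1482 features differed, 620 higher and 862 lower, and 623 by at least 2-fold, with groups that did not overlap for 38.7% (chance 10%). Array weights gave 2411. The CNS enrichments of the wild-type and mutant lines share no arrays, and across genes, which are not independent replicates, they correlated at r = 0.835 and rho = 0.720. Both lines called 463 features higher in CNS cells, where 89.9 would be expected from independent lists, and 777 lower against 157 expected, with 6 in opposite directions.

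**Figure D2:**
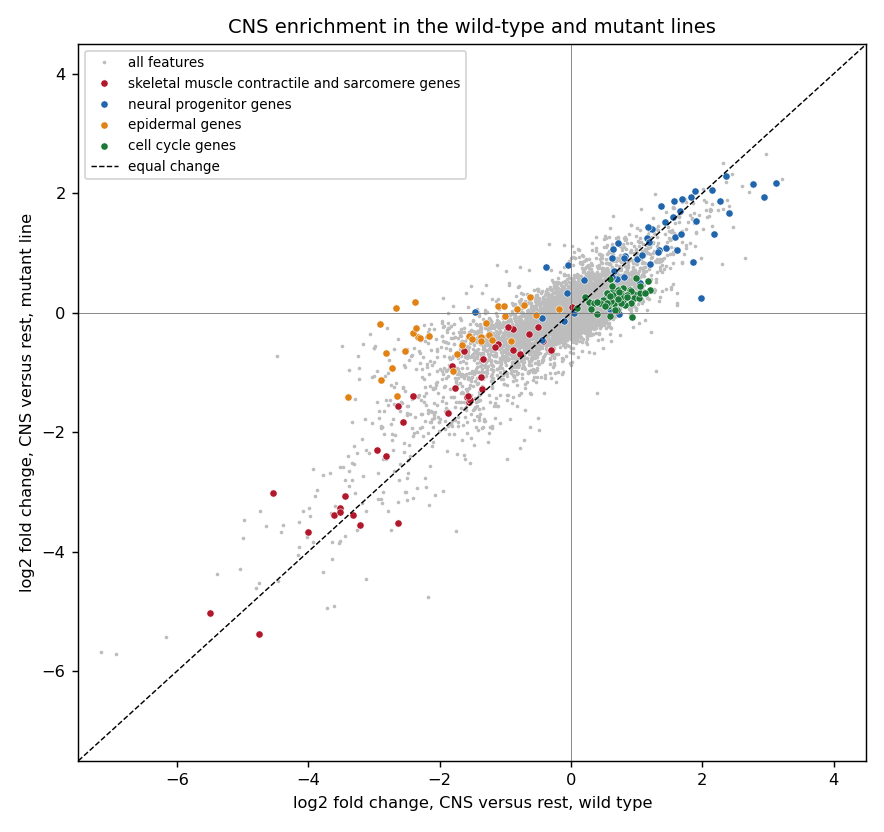
Log2 fold change of CNS cells against the rest in the mutant line (y axis) by that in the wild-type line (x axis), for 9548 features (grey) and 4 gene lists (colours), with a dashed line where both are equal. Sarcomere genes lay low in both lines (means -2.12 and -1.79), while epidermal genes averaged -1.76 in the wild type and -0.38 in the mutant.

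The mutant and wild-type miR-124 lines were then compared within each fraction, to ask what differs in embryos with mutant Dicer. The targeted gene dicer1 averaged 140 ± 60.2 in mutant and 245 ± 18.3 in wild-type CNS cells, a log2 fold change of -0.81 (SE 0.26, adjusted p = 0.022), and 93.5 ± 22.8 against 198 ± 87.9 in the GFP-negative cells (-0.90, SE 0.26, adjusted p = 0.0117). In the miR-206 line it averaged 160 ± 16.6 in muscle cells and 149 ± 33.0 in the rest. Whether its probe set lies in the mutated part of the gene is not given in the sources used here. The CNS call ended without wild-type GFP-positive replicate 2 (-0.77, adjusted p = 0.064) or 3 (-0.79, adjusted p = 0.0592) and without mutant GFP-positive replicate 1 (-0.68, adjusted p = 0.0917) or 3 (-0.63, adjusted p = 0.111). The GFP-negative call ended without wild-type replicate 2 (-0.60, adjusted p = 0.084) or mutant replicate 3 (-0.75, adjusted p = 0.0632). Of the 5 measured genes of the microRNA machinery, dicer1 and dgcr8 (-0.91), a partner of Drosha, were lower and drosha itself was higher (0.44) in mutant CNS cells (1 higher and 2 lower also when adjusted over the list alone; adjusted p = 0.484 for the list). The last 2 genes are named because the count is small and were chosen after their values were seen.

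In mutant CNS cells the chaperone gene hspa8b rose from 77.8 ± 13.2 to 1162 ± 195 (3.65, SE 0.25, adjusted p = 4.39e-09), the trunk gene hoxc8a from 130 ± 50.2 to 1342 ± 275 (3.25) and the reductase gene akr1b1.2 from 33.3 ± 7.78 to 432 ± 61.8 (3.19). Other large rises were those of the endoplasmic reticulum chaperone gene hsp90b1 (2.66), the retinoic acid degrading enzyme gene cyp26a1 (2.66), the actin-binding gene pfn1 (2.65), cldni (2.61; 1284 ± 344 against 211 ± 119) and tagln2 (2.59). The gap junction gene gja1b fell from 623 ± 86.6 to 24.3 ± 3.08 (-3.98), and the lysosomal protease gene ctsba from 567 ± 56.9 to 49.4 ± 20.2 (-3.21). Smaller falls were those of cpa4 (-2.27), gulp1a (-2.17), irf1b (-2.10), the retinal factor gene rx2 (-2.08), the calcium channel gene cacna1ha (-2.06) and rsrp1 (-2.02).

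Ribosomal protein genes fell almost throughout in mutant CNS cells, 70 of 72 with 0 higher, or 71 and 0 adjusted over the list alone (mean -0.76, adjusted p = 3.12e-31, and adjusted p = 0.144 with an estimated correlation). The gene rpl30 averaged 3343 ± 105 against 6566 ± 508 (-0.97), rpl13 changed by -1.34 and rpl35 by -1.26. With quantile normalization 41 fell and 1 rose, at a mean of -0.37. Respiratory chain genes fell in 42 of 84 cases with 5 higher, or 46 and 6 adjusted over the list alone (mean -0.38, adjusted p = 2.17e-08, and adjusted p = 0.473 with an estimated correlation), with ndufa6 at -1.46 and cox7c at -1.16. On the same arrays the 98th percentile of intensity was lower, at 1614 ± 19.1 in mutant against 1864 ± 65.9 in wild-type CNS cells, and 1604 ± 26.4 against 1743 ± 107 in the rest. The ratio of the 3' to the middle GAPDH control probe set, which can be a sign of RNA or labelling quality, was higher, at 2.86 ± 0.289 against 2.11 ± 0.148 and 2.49 ± 0.0697 against 1.86 ± 0.228. GAPDH itself was brighter too. Its 3' probe set read 767.5, 589.7 and 843 in mutant against 322.1, 362.6 and 420.2 in wild-type CNS cells. In the rest it read 556.2, 436.6 and 482.7 against 107.6, 84.3 and 280.9. The ratio cannot be told apart from this difference in level. The same ratio of the dap control was 2.37 ± 0.191 against 2.13 ± 0.345 in CNS cells. In the rest it was lower in the mutant, at 2.29 ± 0.194 against 2.70 ± 0.817.

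Extracellular matrix genes rose in mutant CNS cells, 15 of 27 with 0 lower, as adjusted over the list alone (mean 0.66, adjusted p = 8.16e-05, and adjusted p = 0.26 with an estimated correlation), with the protease gene mmp2 at 2.05, its inhibitor gene timp2a at 1.99 and dcn at 1.73. Epidermal genes rose in 15 of 33 cases with 0 lower, the same adjusted over the list alone (mean 0.63, median 0.29, adjusted p = 0.00378, and adjusted p = 0.56 with an estimated correlation), with cfl1l at 2.52, the epidermal stem cell factor gene tp63 at 2.18 and the cadherin gene cdh1 at 1.75. Neuronal genes rose in 16 of 43 with 3 lower, or 18 and 3 adjusted over the list alone (mean 0.39, adjusted p = 0.00259, and adjusted p = 0.492 with an estimated correlation), with the motor neuron gene isl2a at 1.34 and the tubulin gene tuba2 at 1.34. Hox genes rose in 10 of 34 with 0 lower, as adjusted over the list alone (mean 0.43, adjusted p = 0.00422, and adjusted p = 0.492 with an estimated correlation), with the hindbrain gene hoxb1a at 1.48. Immediate early genes fell in 14 of 38 with 3 higher, or 17 and 3 adjusted over the list alone (mean -0.33, adjusted p = 0.00604, and adjusted p = 0.473 with an estimated correlation), with junbb at -0.77, but did not pass with quantile normalization (adjusted p = 0.113). Of 59 cell cycle genes 17 fell and 7 rose, as adjusted over the list alone (mean -0.13, adjusted p = 0.0457, and adjusted p = 0.573 with an estimated correlation). That list did not pass without wild-type GFP-positive replicate 1 (adjusted p = 0.0986) or mutant GFP-positive replicate 2 (adjusted p = 0.114), with quantile normalization (adjusted p = 0.279), without a filter (adjusted p = 0.113) or with a pseudocount of 1 (adjusted p = 0.0539).

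Reported miR-124 targets were higher in the mutant CNS cells, 10 of 33 with 3 lower, as adjusted over the list alone (mean 0.43, adjusted p = 0.0277, and adjusted p = 0.446 with an estimated correlation). They included tagln2 (2.59), iqgap1 (1.99), the calpain gene capn2a (1.70) and the annexin gene anxa5b (1.66), genes also known from skin and mesenchyme, and in the same cells the epidermal and the matrix list averaged 0.63 and 0.66. In the GFP-negative cells the same list had 2 higher and 7 lower members (the same adjusted over the list alone; mean -0.0028, adjusted p = 0.707). Of 8 measured miR-430 targets reported in zebrafish, 3 rose and 0 fell, also adjusted over the list alone, and the list did not pass (mean 0.44, adjusted p = 0.16). Those 3 were the Nodal antagonist gene lft1 (1.65), cd82b (1.60) and the chemokine gene cxcl12b (0.83), named after their values were seen. Neural progenitor genes, 7 higher and 9 lower of 54 (the same adjusted over the list alone), did not pass as a list (mean -0.07, median 0.01, adjusted p = 0.404).

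Between the CNS fractions 3313 features differed, 1838 higher and 1475 lower in the mutant, and 638 by at least 2-fold. The groups did not overlap for 56.1% (chance 10%). The higher share of 55.5% became 32.4% with arrays centred on their medians, as the median of all genes moved from 0.02 to -0.16.

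**Figure D3:**
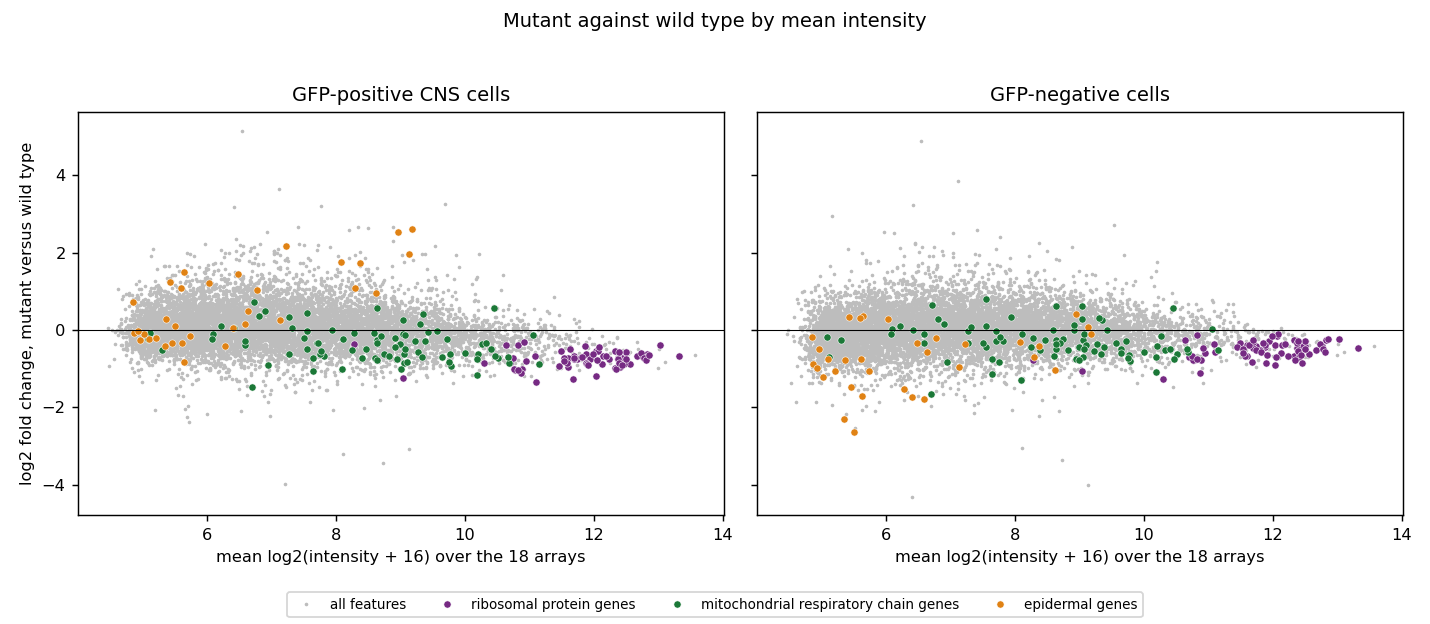
Log2 fold change of mutant against wild type (y axis) by mean log2(intensity + 16) over the 18 arrays (x axis), in CNS cells (left) and GFP-negative cells (right), for all features (grey) and 3 gene lists (colours). Ribosomal protein genes, among the brightest, lay below 0 in both fractions (means -0.76 and -0.52, and -0.37 and -0.25 with quantile normalization).

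In the GFP-negative cells of the mutant, hspa8b rose from 53.4 ± 25.8 to 957 ± 244 (3.84), akr1b1.2 by 3.23, hsp90b1 by 2.57, parp3 by 2.53, the peroxisomal transporter gene abcd3a by 2.24, the nucleoside transporter gene slc29a2 by 2.23, itm2cb by 2.14 and amy2al1 by 2.12. The collagenase gene mmp13a fell from 774 ± 344 to 21.1 ± 5.12 (-4.32), followed by ctsba (-3.05), the cardiac myosin genes myh7 (-2.54) and cmlc1 (-2.18), and the macrophage factor gene spi1b (-2.07). The skin genes krt17 and lye changed by -2.63 and -2.29, and by -3.43 and -2.94 without wild-type GFP-negative replicate 1. The globin gene hbae3 changed by -2.22, a call that ended without mutant GFP-negative replicate 2 (-1.78, adjusted p = 0.0808) and with a pseudocount of 1 (adjusted p = 0.0688).

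Ribosomal protein genes fell in 56 of 72 cases in this fraction, or 62 adjusted over the list alone (mean -0.52, adjusted p = 2.24e-17, and adjusted p = 0.295 with an estimated correlation), and in 32 with 1 higher with quantile normalization (mean -0.25). Hox genes rose in 18 of 34 with 1 lower, or 21 and 1 adjusted over the list alone (mean 0.53, adjusted p = 1.2e-05, and adjusted p = 0.279 with an estimated correlation), with hoxc8a at 1.95 and hoxa9b at 1.80. Cell cycle genes rose in 22 of 59 with 5 lower, or 24 and 5 adjusted over the list alone (mean 0.305, adjusted p = 0.000233, and adjusted p = 0.338 with an estimated correlation), with the thymidylate synthase gene tyms at 1.80 and the condensin gene smc2 at 1.12. Epidermal genes fell in 18 of 33 with 0 higher, or 19 adjusted over the list alone (mean -0.745, adjusted p = 2.98e-05, and adjusted p = 0.424 with an estimated correlation), with krt99 at -1.70 and cldnb at -1.52. Of 10 myeloid genes 8 fell and 1 rose, as adjusted over the list alone (mean -1.28, adjusted p = 0.000119, and adjusted p = 0.0733 with an estimated correlation), with lcp1 at -1.86 and cebpa at -1.66. Sarcomere genes fell in 18 of 38, as adjusted over the list alone (mean -0.47, adjusted p = 5.7e-05, and adjusted p = 0.407 with an estimated correlation), with tpma at -1.06. Respiratory chain genes fell in 34 of 84 with 5 higher, or 36 and 5 adjusted over the list alone (mean -0.31, adjusted p = 2.65e-05, and adjusted p = 0.573 with an estimated correlation).

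Markers of other tissues moved in these cells too. Presomitic genes rose in 7 of 18 cases with 0 lower, or 8 adjusted over the list alone (mean 0.48, adjusted p = 0.033, and adjusted p = 0.608 with an estimated correlation), with tbx16 at 1.74 and cyp26a1 at 1.49. Erythroid genes fell in 8 of 20, as adjusted over the list alone (mean -0.66, adjusted p = 0.000802, and adjusted p = 0.473 with an estimated correlation), with slc25a37 at -1.06. Of 9 cardiac genes 5 fell and 1 rose, also adjusted over the list alone (mean -0.73, adjusted p = 0.0076, and adjusted p = 0.221 with an estimated correlation), with myl7 at -1.94. Endothelial genes fell in 4 of 10, or 7 adjusted over the list alone (mean -0.51, adjusted p = 0.0156, and adjusted p = 0.56 with an estimated correlation), with fli1rs at -1.09. Notochord and floor plate genes fell in 6 of 13, or 7 adjusted over the list alone (mean -0.53, adjusted p = 0.00345, and adjusted p = 0.193 with an estimated correlation), with matn1 at -1.13. Among 6 pronephric genes 5 fell, as adjusted over the list alone (mean -0.74, adjusted p = 0.00543, and adjusted p = 0.234 with an estimated correlation), with slc12a3 at -1.01, which did not pass with a pseudocount of 1 (-1.50, adjusted p = 0.0544). The presomitic call ended without wild-type GFP-negative replicate 3 (0.29, adjusted p = 0.31), without mutant GFP-negative replicate 3 (adjusted p = 0.0763), without the 2 least correlated arrays (adjusted p = 0.0624) and with a pseudocount of 1 (adjusted p = 0.0801). The endothelial call ended without wild-type GFP-negative replicate 3 (-0.36, adjusted p = 0.0935).

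Here 3334 features differed, 1673 higher and 1661 lower, and 550 by at least 2-fold, with groups that did not overlap for 46.1% (chance 10%). Arrays centred on their medians moved the higher share from 50.2% to 37.7%. The mutant effects in the 2 fractions share no arrays and correlated across genes at r = 0.706 and rho = 0.704. Both called 1087 features higher (322 expected from independent lists) and 902 lower (257 expected), with 41 in opposite directions. The fractions are not independent, as they came from the same lines and those of the mutant paired by replicate number. This agreement therefore cannot tell the genotype apart from other differences between the lines or their arrays.

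The interaction asked whether the CNS enrichment itself differed between mutant and wild type. It did for 246 features, 217 of them with a higher and 29 with a lower enrichment in the mutant, and 195 by at least 2-fold. A higher enrichment here includes a weaker depletion from CNS cells. The largest positive differences were those of mmp13a (3.77, SE 0.42, adjusted p = 8.7e-05), pfn1 (2.93, SE 0.41, adjusted p = 0.00083), cldni (2.73, SE 0.50, adjusted p = 0.00375), gpa33a (2.56), tp63 (2.56, but adjusted p = 0.0504 with a pseudocount of 1), postnb (2.51), tagln2 (2.42) and spi1b (2.41). The size for mmp13a depends on the floor, as its 21.1 in the mutant GFP-negative cells lay under the 40th percentile of those arrays (23.2 to 23.9), and it was 3.65 with a pseudocount of 1 and 3.01 with 64. Among those on the negative side were aldh1a2 (-2.58, SE 0.29, adjusted p = 9.53e-05), gja1b (-2.27), gulp1a (-1.75) and the iron-sulfur scaffold gene iscub (-1.47). The count was 380 with a replicate block, although numbers paired only in the mutant line. It was 141 without wild-type GFP-positive replicate 1, 152 without mutant GFP-positive replicate 1, and 159 and 158 without mutant GFP-negative replicates 1 and 3.

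Epidermal genes as a list were less depleted from CNS cells in the mutant, with 9 of 33 differences higher and 0 lower, or 28 higher adjusted over the list alone (mean 1.38, adjusted p = 4.08e-24, and 0.0474 with an estimated correlation), among them cdh1 (2.06) and krt8 (1.80). Their mean in CNS cells against the rest was -1.76 in the wild type and -0.38 in the mutant. The difference held a fall in the mutant GFP-negative cells (mean -0.745) and a rise in the mutant CNS cells (mean 0.63). For myeloid genes, also lower in CNS cells of both lines, the difference was positive in 7 of 10, or 8 adjusted over the list alone (mean 1.47, adjusted p = 1.17e-11, and 0.0313 with an estimated correlation), with spi1b at 2.41. Most of this was their fall in the mutant GFP-negative cells (mean -1.28). In mutant against wild-type CNS cells the list did not pass, with 2 of 10 higher, also adjusted over the list alone (mean 0.20, adjusted p = 0.54). Cell cycle genes had a lower enrichment as a list, with 1 of 59 lower, or 9 adjusted over the list alone (mean -0.44, adjusted p = 1.7e-17, and 0.0317 with an estimated correlation). Most of that was their rise in the mutant GFP-negative cells (mean 0.305), beside -0.13 in mutant against wild-type CNS cells. Extracellular matrix genes, with means of -1.50 and -0.85 in wild-type and mutant CNS cells against the rest, were also less depleted in the mutant. Their difference was positive in 5 of 27 with 0 lower, or 9 and 1 adjusted over the list alone (mean 0.65, adjusted p = 1.3e-08, and adjusted p = 0.0989 with an estimated correlation), with col1a1a at 1.93 and dcn at 1.86. For reported miR-124 targets, lower on average in CNS cells of both lines, the difference was positive in 4 of 33 with 0 lower, or 7 and 0 adjusted over the list alone (mean 0.43, adjusted p = 0.000114, and adjusted p = 0.169 with an estimated correlation), with capn2a at 1.82, iqgap1 at 1.62 and snai2 at 1.44. For dicer1 the difference was 0.10 and did not pass (adjusted p = 0.958).

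**Figure D4:**
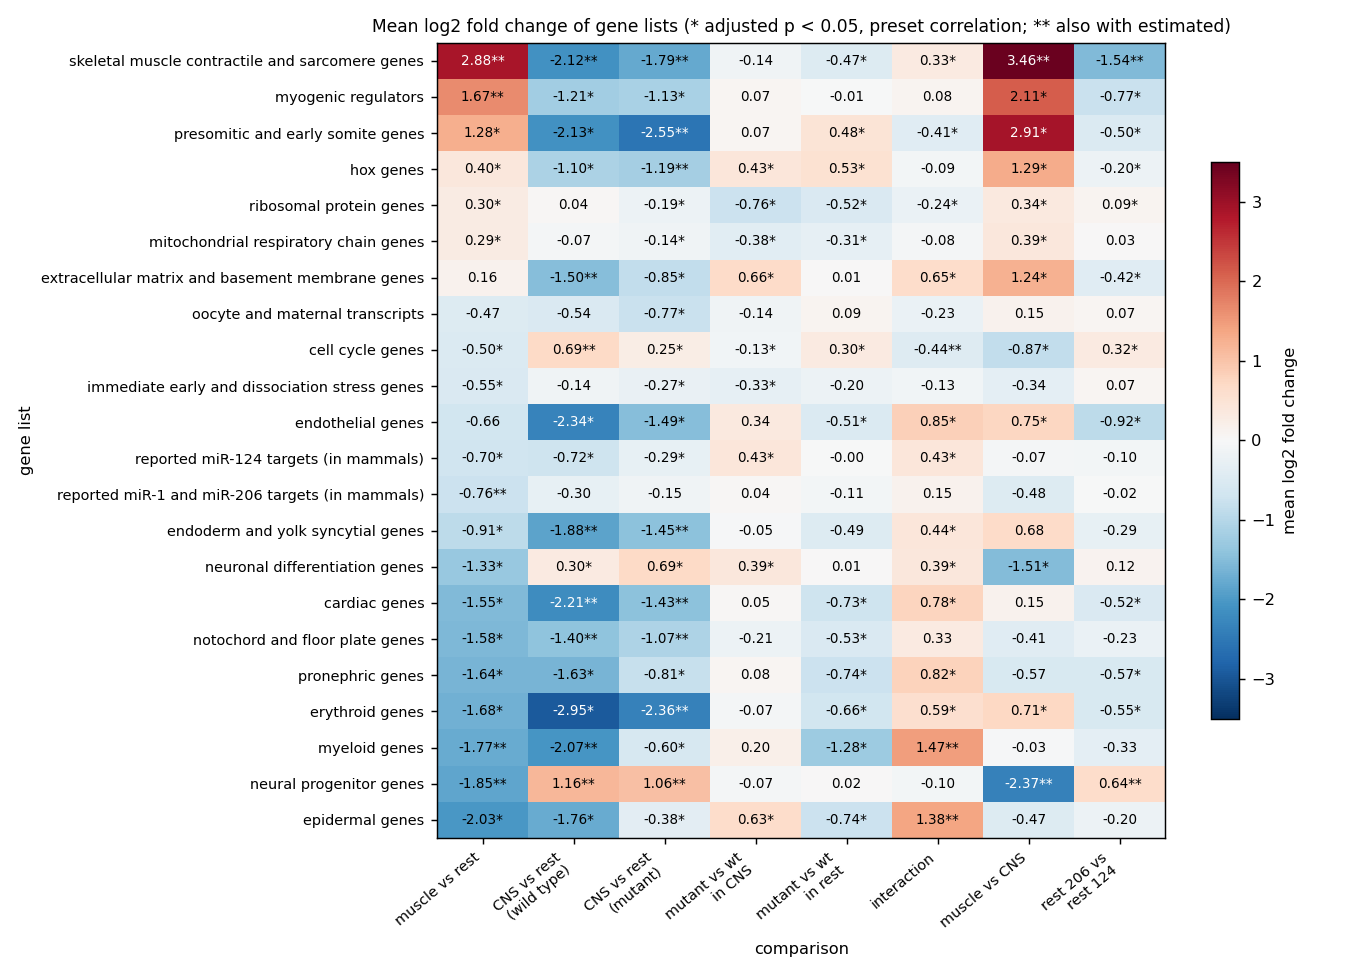
Mean log2 fold change over the measured members of 22 gene lists (y axis) in the 8 comparisons (x axis), as colour and number, with 1 star for an adjusted p under 0.05 at the preset correlation and 2 stars where it also held with an estimated one. Sarcomere genes averaged 2.88 in muscle cells against the rest, and the epidermal interaction was 1.38.

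Muscle and CNS cells came from different wild-type lines. Against CNS cells, muscle cells were higher in smyhc1 (7.08, SE 0.31, adjusted p = 3.01e-13), hsp90aa1.1 (6.31), actc1a (6.03), ttn.2 (6.02), fn1b (6.01), the filamin gene flncb (5.90), acta1a (5.88) and mafbb (5.82). They were lower in sox3, at 55.0 ± 47.8 against 3386 ± 75.5 (-5.78), and in sox19a (-5.40), otx1 (-5.39), en2b (-5.33), pax6a (-5.29), zic5 (-4.82) and myt1a (-4.66). For sox2 (-4.70), 1 of its 2 other probe sets had the same sign.

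All 38 measured sarcomere genes were higher in muscle, and 38 adjusted over the list alone (mean 3.46, adjusted p = 1.03e-32, and 0.0313 with an estimated correlation). Neural progenitor genes were lower in 48 of 54 with 2 higher, as adjusted over the list alone (mean -2.37, adjusted p = 3.57e-23, and 0.0313 with an estimated correlation). All 18 presomitic genes rose, as adjusted over the list alone (mean 2.91, adjusted p = 6.74e-15, and adjusted p = 0.0733 with an estimated correlation), with tcf15 at 4.76. Cell cycle genes fell in 53 of 59, or 54 adjusted over the list alone (mean -0.87, adjusted p = 1.58e-13, and adjusted p = 0.0555 with an estimated correlation). Hox genes were higher in 28 of 34 with 1 lower, or 29 and 1 adjusted over the list alone (mean 1.29, adjusted p = 2.35e-13, and adjusted p = 0.0733 with an estimated correlation). Respiratory chain genes rose in 41 of 84 with 1 lower, or 42 and 1 adjusted over the list alone (mean 0.39, adjusted p = 1.74e-07, and adjusted p = 0.492 with an estimated correlation). Of the 30 lists 12 passed in this comparison, 2 of them also with an estimated correlation, and not all are given here. In total 4242 features differed, 1747 higher and 2495 lower, and 1530 by at least 2-fold. Groups did not overlap for 56.7% (chance 10%), and the higher share moved from 41.2% to 52.3% with arrays centred on their medians. For dicer1 the change of -0.57 did not pass (adjusted p = 0.0856), but it did with a replicate block (adjusted p = 0.0184), with only the arrays compared (0.00393) and with array weights (0.0393).

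The GFP-negative cells of the wild-type lines differ in line and in which tissue had been sorted into the other fraction. Those of the miR-124 line still held neural transcripts. On its 3 GFP-negative arrays sox3 read 1494, 1573 and 1310, against 3331, 3355 and 3472 in CNS cells. For pax6a the readings were 66.2, 177.1 and 146.9 against 875.4, 894.5 and 1015.3. The rest of that line was thus not free of neural transcripts, which also limits its CNS comparison. The GFP-negative cells of the miR-206 line were higher in en2b (1.79), en2a (1.70), six3a (1.70), nr2e1 (1.65), sox19a (1.63) and rx3 (1.51), and lower in smyhc1 (-4.11), atp2a1 (-2.99), hsp90aa1.1 (-2.88), ttn.2 (-2.78), tnnc2.2 (-2.74), tpma (-2.60) and myl1 (-2.57). Sarcomere genes were lower in 30 of 38, or 32 adjusted over the list alone (mean -1.54, adjusted p = 2.47e-40, and 0.0313 with an estimated correlation). Neural progenitor genes were higher in 22 of 54, or 32 adjusted over the list alone (mean 0.64, adjusted p = 7.66e-21, and 0.0313 with an estimated correlation). Cell cycle genes were higher in 9 of 59, or 26 adjusted over the list alone (mean 0.32, adjusted p = 2.71e-13, and adjusted p = 0.0555 with an estimated correlation). In all, 12 of the 30 lists passed in this comparison, 2 of them also with an estimated correlation. Lists beyond those given here therefore moved as well. The GAPDH ratio was 1.46 ± 0.260 against 1.86 ± 0.228. That of the dap control was 2.07 ± 0.237 against 2.70 ± 0.817. Altogether 585 features differed, 213 higher and 372 lower, and 175 by at least 2-fold, and groups did not overlap for 17.7% (chance 10%). The count was 359 without GFP-negative replicate 1 of the miR-206 line, 371 with array weights and 198 with only the arrays compared.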

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

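The tests of batches, of poorer separation, of chance coincidence and of the reporter probe set were chosen only after the results were seen.

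Results of the interaction stood out because the CNS enrichment differed between the mutant and wild-type lines in a test of that difference, for 246 features. The named differences were 3.77 for mmp13a, 2.93 for pfn1, 2.73 for cldni, 2.56 for gpa33a, 2.56 for tp63, 2.51 for postnb, 2.42 for tagln2 and 2.41 for spi1b. On the negative side they were -2.58 for aldh1a2, -2.27 for gja1b, -1.90 for vox, -1.75 for gulp1a, -1.72 for rx2, -1.49 for mllt3, -1.47 for iscub and -1.29 for hoxa9b. With a pseudocount of 1, tp63, rx2, hoxa9b and mllt3 did not pass (adjusted p = 0.0504, 0.174, 0.0901 and 0.0843). The vox difference did not pass without wild-type GFP-positive replicate 2 (-1.83) or 3 (-1.88), wild-type GFP-negative replicate 3 (-1.67), mutant GFP-positive replicate 2 (-1.67) or 3 (-1.81), or mutant GFP-negative replicate 1 (-1.75) or 3 (-1.81). That of mllt3 did not pass without wild-type GFP-positive replicate 1 (-1.64), 2 (-1.55) or 3 (-1.27), wild-type GFP-negative replicate 2 (-1.44) or 3 (-1.42), mutant GFP-positive replicate 2 (-1.48) or 3 (-1.29), or mutant GFP-negative replicate 1 (-1.64), 2 (-1.54) or 3 (-1.28).

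Among gene lists, the mean difference was 1.38 for epidermal, 1.47 for myeloid and -0.44 for cell cycle genes, which passed with either correlation. Extracellular matrix genes differed by 0.65 and reported miR-124 targets by 0.43, with an adjusted p = 0.0989 and 0.169 with an estimated correlation. Endothelial genes differed by 0.85, with 1 of 10 past the threshold and 4 adjusted over the list alone (adjusted p = 6.59e-06, and adjusted p = 0.279 with an estimated correlation). Pronephric genes differed by 0.82, with 1 of 6 higher and 3 adjusted over the list alone (adjusted p = 0.000435, and adjusted p = 0.135 with an estimated correlation). Cardiac genes differed by 0.78, with 4 of 9 higher, as adjusted over the list alone (adjusted p = 4.48e-05, and adjusted p = 0.0733 with an estimated correlation). Erythroid genes differed by 0.59, with 0 of 20 past the threshold and 3 higher adjusted over the list alone (adjusted p = 8.11e-05, and adjusted p = 0.392 with an estimated correlation). For neuronal genes the mean was 0.39, with 4 of 43 higher and 1 lower, or 9 and 1 adjusted over the list alone (adjusted p = 9.56e-05, and adjusted p = 0.374 with an estimated correlation). For ribosomal protein genes it was -0.24, with 0 of 72 past the threshold, also adjusted over the list alone (adjusted p = 8.51e-10, and adjusted p = 0.473 with an estimated correlation), -0.14 without wild-type GFP-negative replicate 3 and -0.12 with quantile normalization. For sarcomere genes it was 0.33, with 2 of 38 higher and 3 adjusted over the list alone (adjusted p = 0.000591, and adjusted p = 0.48 with an estimated correlation). It was 0.21 without wild-type GFP-negative replicate 3 and 0.19 without mutant GFP-negative replicate 2, and did not pass with a pseudocount of 1 (adjusted p = 0.069). Presomitic genes differed by -0.41, with 1 of 18 lower, or 3 with 1 higher adjusted over the list alone (adjusted p = 0.00684, and adjusted p = 0.533 with an estimated correlation). They did not pass without wild-type GFP-positive replicate 2 (-0.28) or wild-type GFP-negative replicate 3 (-0.21), and without wild-type GFP-negative replicate 1 the mean was -0.63. Endoderm and yolk genes differed by 0.44, with 0 of 9 past the threshold and 2 adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.262 with an estimated correlation). They did not pass without wild-type GFP-positive replicate 1 (0.34), wild-type GFP-negative replicate 1 (0.40), mutant GFP-positive replicate 1 (0.35) or mutant GFP-negative replicate 2 (0.38), with a pseudocount of 1 (adjusted p = 0.146) or without a filter (adjusted p = 0.0869).

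Ribosomal protein genes were lower in mutant than in wild-type CNS cells, at a median of -0.74. Bright probe sets in general were also lower. The 10000 gene sets matched on intensity had a median of -0.39 (central 95% from -0.50 to -0.32), and 0 of them reached the ribosomal median. A compression of bright probe sets may account for part of the shift, and whether it accounts for all of it was not settled. The sets were drawn gene by gene, while the estimated correlation within the list was 0.583. Genes at the bright end may also have had few brighter ones to be matched with. The highest intensity on an array was lower too, at 8449 to 8902 in mutant against 12057 to 14909 in wild-type CNS cells. Scaling between arrays does not account for the whole shift by the bound of -0.25 set in advance, as the mean was -0.37 with quantile normalization. The labels of 0 samples name a batch or date, so a batch of the mutant arrays cannot be told apart from the genotype. Some technical values differed between these arrays. The bioDn control probe set read 704, 716 and 733 on the mutant against 1115, 1004 and 992 on the wild-type CNS arrays. The GAPDH ratio was higher in the mutant (2.86 ± 0.289 against 2.11 ± 0.148), where the GAPDH probe sets were also brighter, while the dap ratio was 2.37 ± 0.191 against 2.13 ± 0.345. The genotype itself stays among the open explanations and was not tested.

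Epidermal genes were higher in the mutant GFP-positive sort (mean 0.63), while in the mutant GFP-negative cells they were lower (mean -0.745). If epidermal cells had entered the sort, each rise divided by the level in the mutant GFP-negative cells (a ratio, not a share of cells, as these are a mixture) would be about equal for all their genes, and its median over the 15 genes that rose was 51.5%. The test set in advance, by which 0 of the 5 brightest epidermal genes lay below 25.8%, or 0.5 times that median, by more than 2 standard errors, decides nothing, since the bound came from the genes that rose and those 5 are among them, and over all 33 members the ratio ran from -107.8% ± 10.2 (krt99, a dim gene) to 100.7% ± 41.4 (cldna, SE), so epidermal cells in the sort and a change within the CNS cells cannot be told apart. A poorer separation of all cell types alike would put the ratios above 0. The median ratio was -4.07% for muscle genes (95% bootstrap interval -7.27 to -0.81) and -0.96% for erythroid genes (-3.14 to -0.02). It was 16.2% for extracellular matrix (9.11 to 33.0) and 5.07% for endothelial genes (0.54 to 17.6), with 8.70% for myeloid (-10.8 to 45.0) and -0.05% for presomitic genes (-4.34 to 1.45). Muscle and erythroid genes thus showed no rise. The bound of 0 was added once the values were known, and the intervals for muscle and erythroid genes overlap that of all epidermal genes (19.1%, -4.35 to 45.6). The intervals resample genes and not arrays, so they do not measure the spread between sorts. Single arrays showed no rise either. On the 3 mutant CNS arrays smyhc1 read 23.6, 4.4 and 6.7, against 872.5, 739.9 and 933.3 in the mutant rest. For hbae3 the readings were 1.9, 1.9 and 2.2 against 1129.7, 493.4 and 1433.8. For muscle and erythroid genes these values argue against a poorer separation of all cell types alike. An entry of some cell types alone stays open.

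A set of 20 features was shifted at least 4-fold in the same direction in both fractions of the mutant, 16 higher and 4 lower, and 0 in opposite directions. Independent lists of the 49 and 36 features shifted in each fraction would share 0.102, fewer than the 20 seen. The fractions came from the same lines, and those of the mutant paired by replicate number, so the lists are not independent. How many shared features chance would give in such linked fractions is not known, so a chance coincidence of shifts is not excluded by this count. The named ones, singled out after their values were seen, were hspa8b, akr1b1.2, hsp90b1, itm2cb, parp3, amy2al1, mif, slc29a2, abcd3a, si:ch211-156b7.4 and ctsba, and 0 of the 20 passed the interaction. Sequence variants under single probe sets could give such shifts, but 0 of these genes had a second probe set above the filter, so they cannot be told apart from changes in expression. The genotype stays open, as do other differences between the lines, and neither was tested.

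Outside the main measurement, a control probe set for a foreign sequence was brighter in the GFP-positive than in the GFP-negative array of all 9 same-numbered pairs, with a lowest ratio of 6.50. It averaged 455 ± 104 against 64.7 ± 13.7 in the miR-206 line, 1890 ± 170 against 128 ± 6.4 in the wild-type and 1438 ± 398 against 148 ± 6.15 in the mutant miR-124 line. Whether it reads the reporter transgene stays open: 9 of 9 pairs and 0 of the other foreign control probe sets (45 in all) showed this, but among those others a probe set named for EGFP was brighter in only 5 of 9 pairs, with a highest intensity of 18.8, and what the first one measures is not given in the sources used here.

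Other splits of the samples were tried for each comparison. With 10 splits of 6 samples (for the interaction, of 6 same-numbered pairs), and 1 of them, the real one, as large as the real result in each comparison, they are too few for a share under 0.05. Each other split also mixes the real groups, so a real difference widens the spread within the mixed groups and lowers the count. The low counts of the other splits are therefore not a chance level. The real counts and the highest of the other splits were 3456 and 1 for muscle against rest, 3129 and 0 for wild-type CNS against rest, 1482 and 0 for mutant CNS against rest, 3313 and 0 for mutant against wild type in CNS cells, 3334 and 0 in the rest, 246 and 0 for the interaction, 4242 and 0 for muscle against CNS, and 585 and 4 for the GFP-negative cells of the wild-type lines.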

How the results depend on the processing

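Only the setting that left out both least correlated arrays was chosen after the results were seen. Of 117 list calls, 28 held and 89 were lost with an estimated correlation, 111 held with quantile normalization and as many without a filter, 113 with a pseudocount of 1, 115 with 64, 114 without the least correlated arrays and 117 with a replicate block. Of 514 named values, some of which never passed, 485 kept their sign and their side of the threshold with a pseudocount of 1, 506 with quantile normalization, 512 with arrays centred on their medians, 489 with only the arrays compared, 501 with array weights and 513 with a replicate block.

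A fold change of at least 2 left 1282 features for muscle against rest, 1133 for wild-type CNS and 623 for mutant CNS against rest, 638 and 550 for mutant against wild type in CNS cells and the rest, 1530 for muscle against CNS and 175 for rest against rest, by its own construction. Array weights gave 2411 for mutant CNS against rest (1482 otherwise) and 371 for rest against rest (585 otherwise), where a fit of only the arrays compared gave 198, and the replicate block gave 380 for the interaction (246 otherwise); the cause was not tested. Leaving out 1 array gave 141 (without wild-type GFP-positive replicate 1) to 317 (without wild-type GFP-negative replicate 1) for the interaction and 359 (without miR-206 GFP-negative replicate 1) to 636 (without its replicate 2) for rest against rest; the cause was not tested.

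Of the dicer1 changes that did not pass, 3 turned sign. In muscle against rest it was -0.0299 without both least correlated arrays, and -0.0299 to 0.256 without 1 array (lowest without miR-206 GFP-negative replicate 1). In the interaction it was -0.0492 with array weights, -0.20 without the least correlated arrays, and -0.20 (without wild-type GFP-negative replicate 2) to 0.41 without 1 array, and in rest against rest 0.13 without the least correlated arrays. That of wild-type CNS against rest kept its sign, and passed without those arrays (0.67, adjusted p = 0.0415). The ribosomal list in rest against rest (0.09) ranged from -0.0302 (without miR-206 GFP-negative replicate 1) to 0.16 without 1 array, and was -0.0061 without wild-type miR-124 GFP-negative replicate 3; the cause was not tested. Sets of genes with microRNA sites were not run. Probe sets near the background, where the pseudocount sets the size of a change, limit small folds.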

Other observations

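Further groups moved in the sorts. Pronephric genes, of the embryonic kidney, fell in all 6 measured cases in muscle cells, as adjusted over the list alone (mean -1.64, adjusted p = 0.000197, and adjusted p = 0.115 with an estimated correlation), with the podocyte gene podxl at -2.03. In wild-type CNS cells 5 of 6 fell, as adjusted over the list alone (mean -1.63, adjusted p = 0.000114, and adjusted p = 0.101 with an estimated correlation), with the cadherin gene cdh17 at -2.07. Notochord and floor plate genes fell in 10 of 13 cases in muscle cells with 2 higher, as adjusted over the list alone (mean -1.58, adjusted p = 4.43e-05, and adjusted p = 0.0733 with an estimated correlation), with col2a1a at -4.05, foxa2 at -2.72 and the hedgehog ligand gene shha at -2.63. Cardiac genes fell in 7 of 9 in muscle cells with 2 higher, as adjusted over the list alone (mean -1.55, adjusted p = 0.00174, and adjusted p = 0.144 with an estimated correlation), with myh7 at -2.72. The 3 measured hatching gland genes, too few for the list test, fell in muscle and in wild-type CNS cells (3 of 3 also adjusted over the list alone), with klf17 at -2.72 and -3.33, cd63 at -1.14 and -0.70, and xbp1 at -0.64 and -0.68, named after their values were seen.

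In no comparison did 8 of the lists pass. Their lowest adjusted p over the 8 comparisons was 0.0607 for p53 response, 0.0953 for reported miR-430 targets, 0.118 for microRNA machinery, 0.122 for germ plasm, 0.125 for neural crest, 0.148 for glycolytic, 0.152 for hypoxia and 0.305 for histone genes. Reported miR-1 and miR-206 targets passed in muscle against rest and in none of the other comparisons, where 0.0612 for muscle against CNS was the lowest.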
